A study of Nicotiana tabacum with 5 samples.

How the data were processed

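The labels describe tobacco plants grown at 23 °C with 14 h light and 10 h dark, leaves sprayed daily with 100 µM MeJA or mock solution, and total RNA from leaf amplified and labelled with Cy3. Per the labels, RNA of 3 replicates was mixed for each treatment, so that the 5 groups hold 1 array each. Groups came from the sample titles, except that the sample titled control at 0 weeks was taken as mock, its treatment label, and the columns of the processed table were matched to samples by the sample number that both carry. Per the file headers, the scanner files hold intensity values extracted with Agilent Feature Extraction 11.5.1.1; the submitters' processing notes name version 10.7. The processed signal is background-subtracted and not scaled between arrays. The deposited table holds the same intensity values per probe and normalized log2 values that the authors made; from the values, these are the log2 of the processed signal less each array's 75th percentile, a method not stated in the sources used here. Values recomputed from the scanner files lay within 0.01 of the deposited log2 values for 99.9% of probes on the array where fewest did.

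Each array had 45220 spots, of which 43803 were not controls, and the deposited table held 43664 probes that are not controls; 95 probes of the scanner files are not in that table and were left out. Spots called outliers by the extraction software, between 7 and 45 per array, were left out, and no spot was saturated (0 on each array). Spots of a probe were averaged on the log2 scale, and each array's 75th percentile over non-control probes was subtracted. Replicate spots of 11 probes had a median SD of 0.05 to 0.09 log2, and the spot error of a difference combined Feature Extraction's error model over both arrays. The number of arrays limits the precision. A difference was taken as measured where a probe was well above background on both arrays, and as a bound against the array's lowest signal well above background where it was so on 1; bounds that gave no direction were dropped. Signal was well above background on all 5 arrays for 21464 probes and on at least 1 for 31057.

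Probes were grouped into 34366 gene units by UniGene cluster, otherwise by transcript assembly or sequence identifier, with the median over the probes of a unit. Units with different identifiers may stem from the same gene, and list counts, intervals and percentiles took them as separate. Names in the files rest on sequence similarity, 7744 units had an informative one, and 2 probes had a gene symbol, so a name states resemblance. What counts as an informative name was made precise after the annotation was seen. Mock at 0 and 1 week lay on slide 1, in scan 1, and the other 3 arrays on slide 2, in scan 2. Of the values per sample in the deposited table, the 5 columns of extraction flags were not used, since the scanner files hold the flags themselves; the intensity columns served for checking.

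Before the data were examined, groups, comparisons, alternatives, gene lists and the rule for named genes were fixed. Comparisons were MeJA against mock at 1 week and at 2 weeks, the overlap of both, the effect averaged over both weeks, mock over time, the MeJA difference against the change over time in mock, and the change of the effect between weeks. Probes counted from a 2-fold difference, with a 4-fold alternative; the single comparisons carry no p-value. The averaged effect was fitted with limma 3.58.1 in R 4.3.3, with week and treatment as terms, a variance trend and Benjamini-Hochberg adjustment at 0.05, over probes well above background on at least 2 of 4 arrays. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Named genes were up to 3 per list with the largest mean difference of 1 sign in both weeks, the 10 highest and 10 lowest with a name in each week and in mock at 2 against 0 weeks, and the 5 largest bounds each way present in both weeks.

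The 37 lists were matched as text patterns on names and descriptions. They covered jasmonate biosynthesis and signalling, nicotine and polyamine synthesis, proteinase inhibitors and anti-herbivore proteins, pathogenesis-related proteins, phenylpropanoid and terpenoid synthesis, antenna proteins, photosystems, the Calvin cycle, chlorophyll synthesis and breakdown, senescence-associated genes, cysteine and aspartic proteases, autophagy and nitrogen. They further covered NAC, WRKY, MYB and AP2/ERF factors, ethylene, abscisic acid, auxin, cytokinin and gibberellin, antioxidant enzymes, peroxidases, heat shock proteins, cytosolic and plastid ribosomal proteins, cell division and histones, cell wall, starch and sugar, lipid transfer and cuticle, glandular trichomes, vascular and phloem markers, plastid and mitochondrial genome transcripts, and common reference genes. A list's higher and lower counts include bounds, while its median, its bootstrap interval over genes (2000 draws) and its percentile among 10000 random lists, matched in 20 bins of mean expression, use genes measured on both arrays; this definition was settled after list values had been seen. At least 3 measured genes were needed, which 35 lists had, giving 70 medians over both weeks.

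Alternatives fixed beforehand were normexp background correction with offset 50, quantile normalization, scaling by the median of probes well above background on all arrays, the deposited values, filters on dim probes, the fold threshold, the brightest probe of a gene, and limma without the week term or the variance trend. The scanner files lack the mean signal planned for normexp, so it ran on median signal and median local background. Added after the data were seen were scaling by 4 of the 8 spike-in probes with signal on all arrays (the 4 brightest, where signal may be compressed, were left out, and scaling was repeated with them), MeJA at 2 weeks against mock at 1 or 0 weeks, limma with the slide as block, within slide 2 and without the 2-week mock array, all 3 without a week term, and list medians with genes at their bound. The list step was tested on simulated data of 30 genes by 100 lists: with no shift 4 lists passed the upper limit and 0 the lower, and a shift of 0.25 log2 passed for 65 and of 0.5 for 100. The limma step ran on simulated data of 26620 probes with an array SD of 0.3, with 100 probes changed at each true log2 difference of 1 and 3. It recovered 39 of 100 at 1 and 100 of 100 at 3, with 6 false calls. The simulated SD was the same for every probe, and no effect changed between weeks. In the measured data the effect changed between weeks with an SD of 1.16 over probes, so these rates do not carry over to the real fit.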

Results

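Leaves of tobacco (Nicotiana tabacum) were sprayed every day with 100 µM methyl jasmonate (MeJA), the volatile ester of the wound and defence hormone jasmonic acid, or with a mock solution. Transcripts were read on 1-colour Agilent arrays. There were 5 groups with 1 array each, mock at 0, 1 and 2 weeks and MeJA at 1 and 2 weeks, and each array carried RNA mixed from 3 replicates. The sample of 0 weeks is titled control and carries the treatment label mock. No replicate array existed, so no difference between groups could be set against a replicate spread. Errors given here are technical spot errors, which had a median of 0.21 log2 and a 95th percentile of 0.33 for the difference at 1 week. Signal was well above background for 61.8% of probes in mock at 0 weeks, 61.8% in mock at 1 week, 57.0% in MeJA at 1 week, 65.4% in mock at 2 weeks and 51.5% in MeJA at 2 weeks. The 75th percentile of signal on these arrays was 997, 1021, 1527, 2499 and 881 intensity units. All differences are log2 MeJA minus mock unless another pair is named, and a gene counts as higher or lower from a 2-fold difference. For each gene list, the median is over genes measured on both arrays, and its percentile is its place among 10000 random lists of equal size and similar brightness. That percentile describes these arrays and is no test across plants.

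The first comparison, MeJA against mock at 1 week, asked which transcripts differed after a week of hormone. A trypsin and protease inhibitor family gene (Nta.6641), of a class that blocks digestive proteases of insects, was 102-fold higher in MeJA, a difference of 6.67 ± 0.30 (spot error) that was 5.58 under normexp background correction. Ornithine decarboxylase (Nta.1222), which makes the putrescine used for polyamines and nicotine, was higher by 4.40, and the MYB factor NtMYBJS1 (Nta.5108), named in the annotation as induced by methyl jasmonate, by 4.26. A MATE efflux family gene (Nta.11459), of a class of membrane exporters, was higher by 3.75, and purple acid phosphatase NtPAP4 (Nta.3922), which releases phosphate from organic esters, by 3.59. Among genes lower in MeJA were alpha-amylase (TC123317, −2.48; TC127104, −2.47), which degrades starch, and WRKY transcription factor 6 (Nta.9442, −2.24).

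Of 26 genes in the nicotine and polyamine list, 14 were higher at 1 week and 0 lower, with a median of 1.42 (bootstrap interval 0.56 to 1.65, 21 genes, percentile 100). A further gene unit annotated as ornithine decarboxylase (TC123396) was higher by 2.94, and arginine decarboxylase 1 (TC165090), which opens the other route to putrescine, by 1.65. In jasmonate biosynthesis, 4 of 10 genes were higher and 0 lower, with a median of 0.65 (0.08 to 2.27, percentile 100). Lipoxygenases, a class that includes the enzymes of the first oxidation step towards jasmonate, differed among themselves: Nta.1810 was higher by 3.69 on the 1 of 2 probes measured, Nta.4212 was higher by 1.54, and Nta.10908 stood at −0.47. Their names do not tell which of them serve that step. Jasmonate signalling had a median of 0.44 (percentile 99.4; 0.72 under spike-in scaling), or 0.25 (percentile 96.2) with genes dim on 1 array at their bound, and 0 of 8 genes were 2-fold higher and 1 lower. The JAZ repressor genes NtJAZ1 (Nta.15526) and NtJAZ2 (Nta.5237, 2 of 3 probes measured) stood at 0.90 and 0.70. The proteinase inhibitor list had 4 genes higher and 2 lower of 15, with a median of 0.27 (percentile 99.2) that was 0.03 (percentile 75.9) with genes at their bound, 0.16 under normexp and 0.55 under spike-in scaling. Its metallocarboxypeptidase inhibitors NtMCPIa (Nta.27513) and NtMCPIb (Nta.5391) were higher by 1.99 and 1.52. Cysteine-rich extensin-like proteins 3 (Nta.7090) and 4 (Nta.7071), structural proteins of the cell wall, were higher by 3.15 and 1.92, in a cell wall list with 11 genes higher and 12 lower of 87.

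Genes annotated as carbonic anhydrase, which interconverts carbon dioxide and bicarbonate, were higher at 1 week (TC136429, 3.55; Nta.8451, 3.42), as were a sexual organ expressed protein (TC124941, 3.42) and a protein kinase family gene (Nta.5522, 3.40). At 2 weeks TC136429 stood at −0.12, Nta.8451 at −0.84 and Nta.5522 at 0.35, while TC124941 was higher by 2.21 (1.02 under quantile normalization). The nitrate transporter NtNRT1.2-t (Nta.3956) was higher by 2.43, while genes annotated as ammonium transporter AMT1;1 were lower (Nta.20054, −1.89; Nta.6115, −2.48 on 1 of 2 probes), in a nitrogen list with 8 genes higher and 8 lower of 42.

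Among WRKY factors, regulators of defence and senescence genes, 7 of 20 were lower and 0 higher at 1 week, with a median of −0.69 (−0.97 to −0.34, percentile 0) that was −0.41 under spike-in scaling, with 3 lower and 1 higher. Under normexp 4 were lower and 0 higher. Pathogenesis-related proteins, antimicrobial proteins of the salicylate and ethylene responses, had 18 genes lower and 1 higher of 74, with a median of −0.25 (percentile 0.37) that was −0.14 under quantile normalization and 0.025 under spike-in scaling. PR-4B (TC164344) was lower, at −1.67. ACC oxidase, the last step of ethylene synthesis, was lower for Nta.11948 (−2.04) and Nta.1097 (−1.47), in an ethylene list with 0 genes higher and 3 lower of 23. Starch and sugar metabolism had 6 genes lower and 1 higher of 51, with a median of −0.30 (percentile 0.12) that was −0.023 under spike-in scaling and 0.043 when this included the brightest spike-ins. NtVPE-1a (Nta.7321), a vacuolar protease of cell death and protein maturation, was lower, at −2.33, urease accessory protein G (TC162753) at −2.25, and inositol-3-phosphate synthase (TC133859), which starts myo-inositol synthesis, at −2.24. Photosynthesis lists showed few 2-fold differences: 1 higher and 1 lower of 44 antenna genes, 2 higher and 1 lower of 71 photosystem genes, and 1 higher and 0 lower of 23 chlorophyll synthesis genes. Senescence-associated genes had 0 higher and 1 lower of 9, with a median of −0.43 (percentile 1.42) that was −0.15 under spike-in scaling. Over all probes with a usable difference, 1297 of 26507 were higher and 1127 lower, and 311 and 109 by 4-fold; spike-in scaling, which moved the median of all probes by 0.27, gave 2330 and 597. The comparison crossed the 2 slides, mock at 1 week lying on slide 1 and MeJA at 1 week on slide 2, so slide and treatment could not be separated in it.

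**Figure D1:**
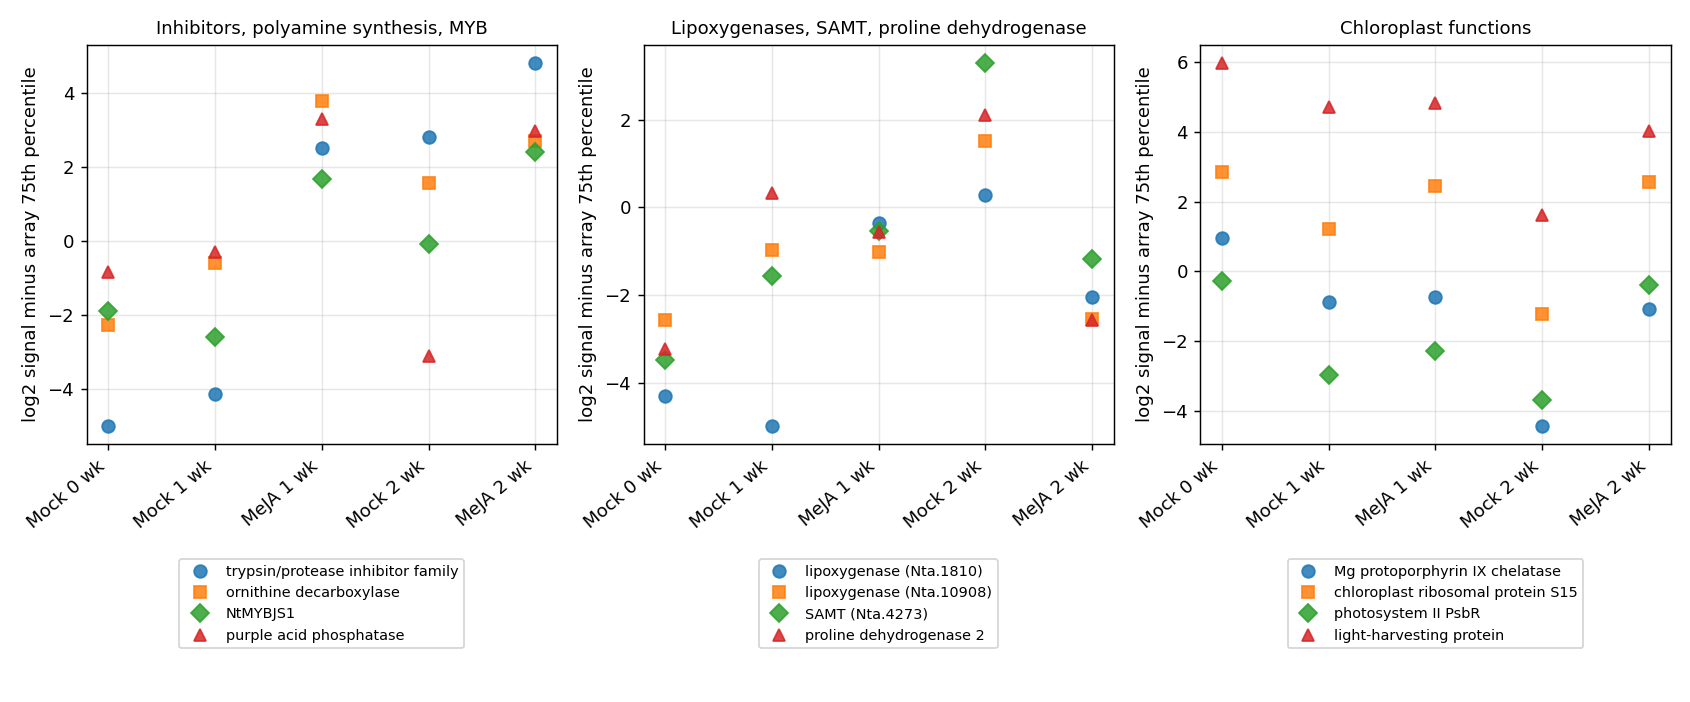
Level of 12 genes on each of the 5 arrays (y axis, log2 signal minus the array's 75th percentile; x axis, group), each point being 1 array and the median over all probes of the gene, so that differences quoted from measured probes alone can deviate; the light-harvesting protein is TC126695 and the lowest level well above background was between −5.05 and −3.42 on an array. The trypsin inhibitor stood at −4.16 in mock and 2.51 in MeJA at 1 week, and at 2.81 in mock and 4.82 in MeJA at 2 weeks.

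The second comparison, MeJA against mock at 2 weeks, repeated the question after another week, on a single slide. The array labelled mock at 2 weeks stood apart from the others, differing from all 4 of them by 2-fold at 3176 of 21464 probes, against 1102 for mock at 0 weeks, 251 for MeJA at 2 weeks, 85 for MeJA at 1 week and 53 for mock at 1 week. NtPAP4 (Nta.3922) was 68.0-fold higher in MeJA, a difference of 6.09 ± 0.23 (spot error), and rubisco activase 1 (TC159223), which keeps the carbon-fixing enzyme active, was higher by 4.78. SAMT (Nta.4273), a name used for salicylic acid carboxyl methyltransferase, was lower, at −4.47, and proline oxidase/dehydrogenase 2, which degrades proline, at −3.89 (TC126898) and −4.43 (Nta.7645, 1 of 2 probes). Lipoxygenase Nta.10908 was lower, at −4.08 (probes −4.13 to −2.37) and lipoxygenase Nta.1810 at −2.33.

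Jasmonate biosynthesis had 6 genes lower and 0 higher of 11 at 2 weeks, with a median of −1.26 (−2.33 to 0.12, percentile 0) that was −1.97 under quantile normalization and 0.54 when MeJA at 2 weeks was set against mock at 1 week. The jasmonate receptor gene coronatine-insensitive 1 (Nta.11244, 1 of 2 probes) was lower, at −1.96, and the signalling list had a median of −0.18 (percentile 10.9), or −0.47 (percentile 1.38) with genes at their bound, −0.58 under quantile normalization and 0.16 against mock at 1 week. In the nicotine and polyamine list 12 genes were higher and 1 lower of 22, with a median of 1.14 (0.36 to 1.62, percentile 98.6) that was 0.49 (percentile 96.4) under quantile normalization, −0.83 under spike-in scaling and 1.89 against mock at 1 week. Arginine decarboxylase 1 (TC165090) was higher by 2.30 (1.42 under quantile normalization) and ornithine decarboxylase (Nta.1222) by 1.15 (0.64). Proteinase inhibitors had 7 genes higher and 0 lower of 13, with a median of 1.44 (−0.26 to 2.00, percentile 99.98) that was 0.55 (percentile 94.5) under quantile normalization, −0.53 under spike-in scaling and −0.21 against mock at 1 week. The trypsin inhibitor (Nta.6641) was higher by 2.00 (1.11 under quantile normalization), and NtMYBJS1 (Nta.5108) by 2.47. NtMCPIa (Nta.27513) stood at 1.59 (0.55 under quantile normalization).

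Chlorophyll synthesis had 16 genes higher and 0 lower of 23, with a median of 1.39 (1.15 to 1.86, percentile 99.98) that was 1.1 under quantile normalization, −0.58 under spike-in scaling and 0.30 against mock at 1 week. Its members included Mg protoporphyrin IX chelatase (TC124328, 3.36), which inserts the magnesium, and the next enzyme, the Mg-protoporphyrin IX methyltransferase (Nta.7052, 2.36). Plastid ribosomal proteins had 27 genes higher and 1 lower of 34, with a median of 1.71 (1.54 to 1.99, percentile 100) that was 1.14 under quantile normalization, −0.26 under spike-in scaling (0.10 with the 4 brightest spike-ins alone) and 0.35 against mock at 1 week. Among its members were proteins S15 (TC144175, 3.80) and S16 (TC164387, 2.43). Cytosolic ribosomal proteins had 101 genes higher and 1 lower of 254, with a median of 0.85 (percentile 100) that was 0.53 under quantile normalization, −1.12 under spike-in scaling and 0.17 (percentile 93.4) against mock at 1 week. Cell division and histone genes had 30 higher and 3 lower of 74, with a median of 0.89 (percentile 100) that was 0.70 under quantile normalization, −1.08 under spike-in scaling and −0.074 against mock at 1 week. Histone H4 (Nta.5337) was higher by 2.98 and cyclin D3;3 (Nta.11736, 1 of 2 probes), which drives entry into the cell cycle, by 2.21.

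Antenna proteins of the light-harvesting complexes had 32 genes higher and 5 lower of 45, with a median of 1.48 (percentile 99.98) that was 0.11 (percentile 60.7) under quantile normalization, −0.49 under spike-in scaling and 0.26 against mock at 1 week. Photosystem and electron transport genes had 46 higher and 0 lower of 69, with a median of 1.38 (percentile 100) that was 0.10 (percentile 63.2) under quantile normalization, −0.59 under spike-in scaling and 0.21 against mock at 1 week. Both medians lay close to 0 once the arrays were given a common distribution. Rubisco and Calvin cycle genes had 16 higher and 0 lower of 23, with a median of 1.22 (percentile 96.1) that was 0.70 (percentile 99.7) under quantile normalization, −0.76 under spike-in scaling and 0.37 against mock at 1 week. Germin-like proteins, oxalate oxidase relatives of the cell wall, were higher (TC146163, 4.71; Nta.7111, 4.48 on 3 of 5 probes), as were beta-galactosidase (Nta.15766, 4.49), the fasciclin-like arabinogalactan FLA9 (Nta.5290, 3.67) and auxin-induced SAUR-like genes (TC167148, 3.57; TC165955, 3.45). Starch and sugar genes had 14 lower and 5 higher of 48, with a median of −0.36 (percentile 0.13) that was −0.72 under quantile normalization and −0.017 (percentile 17.4) against mock at 1 week. The glucose-6-phosphate translocator NtGPT (Nta.6490), which imports sugar phosphate into plastids, was lower, at −3.86. Counts of genes higher and lower depended on scaling too. Under quantile normalization they were 3 and 4 for antenna proteins, 15 and 2 for photosystems, 7 and 1 for the Calvin cycle, 14 and 0 for chlorophyll synthesis, 18 and 0 for plastid and 69 and 1 for cytosolic ribosomal proteins, 28 and 2 for cell division, 5 and 1 for nicotine and polyamines, and 5 and 1 for proteinase inhibitors. Under spike-in scaling the same lists had 1 and 15, 2 and 25, 2 and 6, 1 and 6, 2 and 8, 2 and 149, 1 and 47, 0 and 12, and 1 and 6. The ethylene list had 5 genes lower and 1 higher of 25, with a median of −0.31 (percentile 0.68) that was −0.53 under quantile normalization and 0.031 against mock at 1 week.

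At 2 weeks 5127 of 25584 probes were higher and 3568 lower, and 1481 and 424 by 4-fold, with 4906 and 1688 under normexp background correction. Spike-in scaling moved the median of all probes by −1.97, which turns the sign of differences from 0 to that size, and gave 401 higher and 22574 lower; quantile normalization moved it by −0.15. The difference depended on brightness, with a median of −0.39 in bin 2 of 10 brightness bins of probes and 1.17 in bin 10, the brightest, and of 0.09 in bin 10 under quantile normalization.

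**Figure D2:**
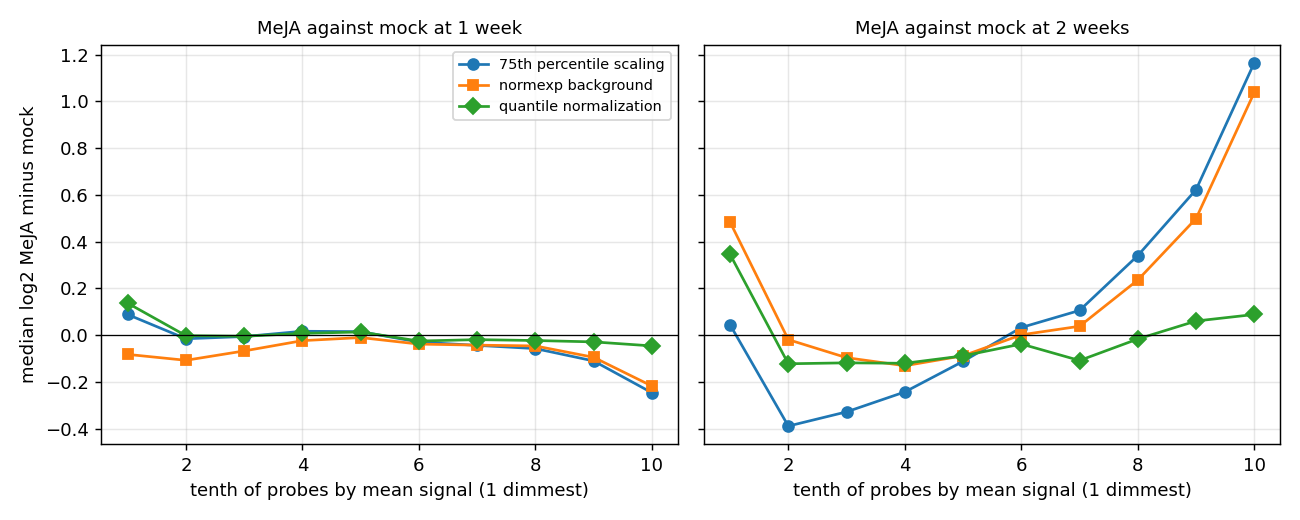
Median log2 difference of MeJA minus mock (y axis) in 10 equal bins of the probes ordered by mean signal (x axis, 1 the dimmest), for 3 ways of processing at 1 week (left) and 2 weeks (right). At 2 weeks the brightest bin stood at 1.17 with 75th percentile scaling and at 0.09 with quantile normalization, while at 1 week it stood at −0.25 with 75th percentile scaling.

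The third comparison asked which differences had the same direction in both weeks, in pools that shared no array. NtPAP4, NtMYBJS1, the trypsin inhibitor, both units annotated as ornithine decarboxylase and NtNRT1.2-t (Nta.3956, 3.00 at 2 weeks) were higher in both. WRKY6 (Nta.9442, −3.19 at 2 weeks), ACC oxidases Nta.11948 (−2.20) and Nta.1097 (−2.52), AMT1;1 (Nta.20054, −2.59) and glutamine synthetase (TC123365, −1.22 and −2.39), which fixes ammonium into glutamine, were lower in both. A further gene annotated AMT1;1 (Nta.6115) was short of 2-fold at 2 weeks, at −0.40 (−1.48 under quantile normalization). Ornithine decarboxylase Nta.1222 was short of 2-fold at 2 weeks under quantile normalization (0.64) and normexp (0.99). Of 22 nicotine and polyamine genes, 11 were higher in both weeks, but 4 under quantile normalization and 0 under spike-in scaling. PR-4B (TC164344) was lower, at −2.44 at 2 weeks (−1.52 under normexp), and 4 pathogenesis-related genes were lower and 0 higher in both (10 and 0 under spike-in scaling). A glutathione S-transferase annotated parA (TC138519), whose class conjugates glutathione to toxins, was not well above background in MeJA and was at least 5.42-fold lower at 1 week and at least 27.3-fold lower at 2 weeks. Of 24327 probes, 338 were higher in both weeks and 308 lower in both, where independent lists would share 178 and 129. Under spike-in scaling 90 were higher in both (23.8 if independent) and 422 lower in both (400 if independent), so that the excess of those lower was small. Under 75th percentile scaling, 92 were higher then lower (128 if independent) and 152 lower then higher (180). Across probes, which are not independent replicates, the differences of the 2 weeks had a Pearson correlation of 0.075 and a Spearman correlation of 0.012.

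A limma fit of week and treatment over these 4 arrays called 271 probes higher and 115 lower in MeJA at a false discovery rate of 0.05, of 26620 tested, with 2241 at an unadjusted p under 0.05. It had 1 residual degree of freedom, took the weeks as repeats, which they are not by design, and leaned on the variance prior: quantile normalization gave 9 and 3, and leaving out the week term gave 0 and 0, with 1031 at an unadjusted p under 0.05. Slide and treatment coincide at 1 week. Fits that also left out the week term gave 12 and 2 with a slide term on all 5 arrays, and 10 and 0 with mock at 0 weeks in place of mock at 2 weeks. Another, within slide 2 and with 1 mock array, called more probes each way than the fit of week and treatment. The counts of these fits cannot be laid to 1 choice.

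**Figure D3:**
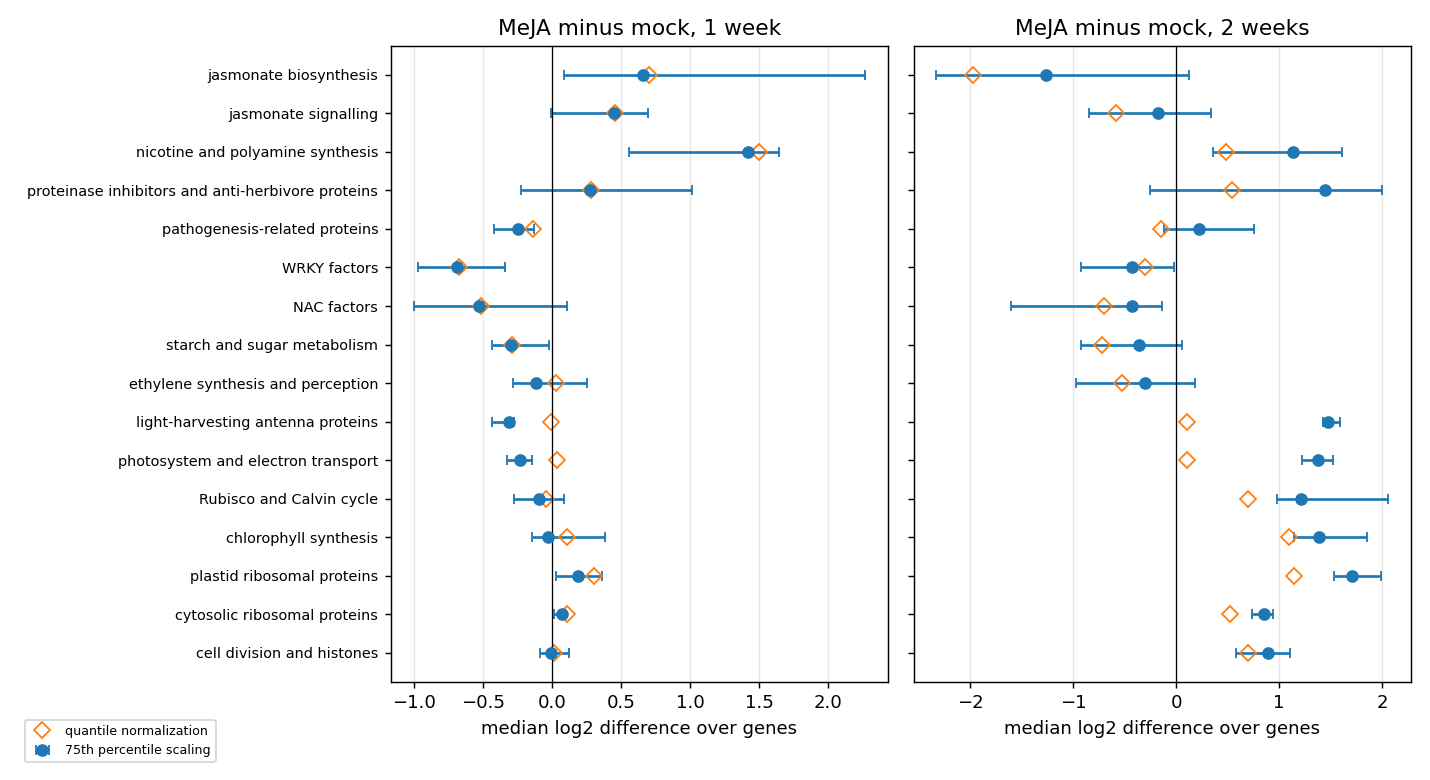
Median log2 difference of MeJA minus mock over the genes of 16 lists (x axis) at 1 week (left) and 2 weeks (right); filled points are the values after 75th percentile scaling with bars for the bootstrap interval over genes, and open diamonds the medians under quantile normalization. At 2 weeks the antenna list stood at 1.48 with scaling, 0.11 under quantile normalization and −0.49 under spike-in scaling (not drawn), and jasmonate biosynthesis stood at 0.65 at 1 week and at −1.26 at 2 weeks, which was 0.54 against mock at 1 week.

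Mock arrays over time gave differences without hormone, in which time and mock spraying go together when the reference is the sample of 0 weeks, titled control. Mock at 0 and 1 week lay on slide 1 and mock at 2 weeks on slide 2, so slide and time could not be separated in differences that involve mock at 2 weeks. Between 0 and 2 weeks SAMT (Nta.4273) was higher by 6.78, the trypsin inhibitor (Nta.6641, 1 of 2 probes) by 6.41 and a cytochrome P450, CYP71AT2v1 (Nta.8705, 1 of 2 probes), by 6.58. Tonoplast intrinsic proteins, water channels of the vacuole membrane, were lower, at −8.07 (TC123331, 1 of 2 probes) and −7.38 (TC126331), and FLA9 (Nta.5290) at −6.61. Jasmonate biosynthesis had 9 genes higher and 1 lower of 12, with a median of 2.34 (percentile 100). Cysteine and aspartic proteases, which degrade leaf protein in senescence, had 16 higher and 1 lower of 31, with a median of 1.16 (percentile 100; 0.77 under normexp and 2.06 under spike-in scaling), after 0.86 (percentile 100) at 1 week. Chlorophyll breakdown genes had 2 higher and 0 lower of 4, with a median of 1.11 (percentile 98.7; 2.01 under spike-in scaling). Under quantile normalization the protease and chlorophyll breakdown medians were 1.09 (percentile 100) and 1.34 (percentile 97.6). Other lists tied to senescence lay inside the central 95% of random lists in that setting. Senescence-associated genes had 3 higher and 2 lower, with a median of 0.21 (percentile 63.4). Autophagy stood at 0.49 (percentile 73.9), NAC factors at 0.53 (percentile 77.3) and WRKY factors at −0.27 (percentile 19.2). Ethylene genes had 11 higher and 1 lower of 28, with a median of 0.94, and starch and sugar genes 23 higher and 8 lower of 53, with a median of 0.92. These were 1.84 and 1.82 under spike-in scaling. Chlorophyll synthesis had 0 higher and 20 lower of 26, with a median of −1.67 that was −1.30 under quantile normalization and −0.77 under spike-in scaling, and plastid ribosomal proteins had 1 higher and 29 lower of 35, with a median of −2.09 that was −1.47 and −1.19. Antenna proteins stood at −1.29, but at −0.06 under quantile normalization and −0.39 under spike-in scaling.

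Between 0 and 1 week of mock spraying 2579 probes of 28392 were higher and 2603 lower, more than between MeJA and mock at 1 week. Between 0 and 2 weeks 6880 of 29796 were higher and 7303 lower, with 4571 and 7401 under normexp and 14638 and 3199 under spike-in scaling, which moved the median of all probes by 0.90. Between 1 and 2 weeks 4203 were higher and 5202 lower, with 2064 and 5168 under normexp and 15195 and 1509 under spike-in scaling, a shift of 0.97.

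The relation of hormone to time was read across probes in pairs without a common array. Genes of chlorophyll synthesis and plastid ribosomes, lower in mock at 1 week than at 0 weeks by medians of −0.44 and −0.66, were among those higher in MeJA at 2 weeks under 75th percentile scaling (1.39 and 1.71; −0.58 and −0.26 under spike-in scaling, the latter 0.10 with the 4 brightest spike-ins alone). The difference at 2 weeks correlated negatively with the mock change from 0 to 1 week (Pearson −0.36, Spearman −0.37, 21653 probes). That difference subtracts mock at 2 weeks, the array that stood apart, so further change over time in mock enters it with the opposite sign. The correlation therefore cannot tell an effect of MeJA against the change over time from a change in that mock array. The difference at 1 week had Pearson and Spearman correlations of −0.053 and −0.052 with the mock change from 0 to 2 weeks (23613 probes). From 1 to 2 weeks the MeJA difference moved up by 4-fold or more at 1425 of 21607 probes and down at 401, a change that no residual allowed to be tested.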

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

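Of the tests weighed in this part, the one of signal scaling on the array labelled mock at 2 weeks was set out before its result was seen, and the others were chosen only after the results they concern had been seen.

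The array labelled mock at 2 weeks differed from the other 4 arrays by 2-fold at 3176 of 21464 probes. Scaling as the whole reason is argued against, because 3149 probes still set it apart under quantile normalization. The 121 probes that split the slides by 2-fold cannot decide on slide or scan. Splits of any 2 arrays against the rest held between 5 and 363 probes, too few to be weighed against 3176. A shift common to slide 2 would not set this array apart, since both MeJA arrays of that slide are among the other 4. Of 164 probes with a 4-fold difference at 1 week, 73.8% kept their direction at 2 weeks once the median of all probes was subtracted. Their median signed difference on that scale was 1.13 (bootstrap interval 0.90 to 1.38). For these probes an exchange of labels with MeJA at 2 weeks is argued against, if differences at 1 week lasted to 2 weeks. The jasmonate biosynthesis median (0.65, then −1.26) and SAMT (Nta.4273, 1.02, then −4.47) turned, as an exchange would have it. An exchange was therefore not excluded. A sample from outside the design, or a change in leaves with 2 weeks of age, may lie behind the distance of this array, and neither was tested.

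Photosynthesis, chlorophyll synthesis and plastid ribosome genes had a median of 1.48 at 2 weeks and of −0.16 at 1 week. Their median for MeJA at 2 weeks against mock at 1 week was 0.26 (0.19 to 0.31, 190 genes), which is consistent with the larger part of the difference lying in the array labelled mock at 2 weeks. For antenna and photosystem genes, quantile normalization left 0.10 (−0.01 to 0.23, 111 genes) of 1.44. That step gives all arrays a common distribution, and took bin 10, the brightest of the brightness bins, from 1.17 to 0.09. A difference shared by many bright probes shrinks under it whatever its source. The small remainder therefore cannot tell array scaling from a change in the leaves. For Calvin cycle, chlorophyll synthesis and plastid ribosome genes, quantile normalization left 0.97 (0.76 to 1.22, 79 genes) of 1.67. That interval spans the bound of the test and keeps scaling open. This division into parts was itself made after the list values were seen, and an effect of MeJA on these genes was not excluded.

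Several genes higher in MeJA at 1 week also stood high on the array labelled mock at 2 weeks, the trypsin inhibitor (Nta.6641) by 6.41 over mock at 0 weeks. RNA of the 2-week MeJA pool in that sample is argued against as the only source of this gene's signal there. A share that large would cap MeJA differences near the 2.00 of this gene, while 2.33% of measured probes (513) exceeded it by over 0.5. A smaller share of such RNA was not excluded. Probes at least 4-fold higher in MeJA at 1 week had a median of 0.95 (0.66 to 1.39, 129 probes) for mock at 2 weeks against mock at 0 weeks, and 49.6% of them were at least 2-fold higher. That interval spans the bound of 1 set for a slide effect, so slide 2, which holds both arrays, and a change with time cannot be told apart for these probes.

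The following results had opposite directions in the 2 weeks, and none of these differences was tested. With MeJA at 2 weeks set against mock at 1 week, each had the direction of 1 week. The 1-week difference uses that mock array too, and both differences cross the slides, so a shared direction is favoured beforehand. This reference also differs in week. It therefore cannot decide whether the opposite directions rest on the array labelled mock at 2 weeks. The median of jasmonate biosynthesis genes differed by −1.92 from 1 to 2 weeks, and was 0.54 for MeJA at 2 weeks against mock at 1 week. Lipoxygenase Nta.1810 (3.69 on 1 of 2 probes, then −2.33) differed by −6.02. SAMT (Nta.4273) stood at 1.02 and then −4.47, a difference of −5.49. BYJ15 (TC156950) stood at 2.02 and then −2.87, a difference of −4.89. A non-specific lipid-transfer protein (Nta.5447) stood at −2.82 and then 2.5 on 1 of 3 probes, a difference of 5.32.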

How the results depend on the processing

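Chosen only after the data had been seen were spike-in scaling, with the 4 brightest spike-ins left out or included, the other reference arrays for MeJA at 2 weeks, limma with the slide as block, within slide 2 and without the 2-week mock array, and list medians with genes at their bound. The deposited values and median scaling left all probe counts within 1.5 times and all 70 list medians inside their interval, as did the brightest probe and genes at their bound for the medians, although the percentiles moved where the report gives both. Quantile normalization left 52 of 70 list medians inside and took 18 outside, and normexp 67 and 3. Of 262 named gene values, quantile normalization moved 59 by more than the spot error and normexp 77, none with a turned call. Under quantile normalization 3 of 61 named genes at 1 week and 10 of 102 at 2 weeks fell short of the 2-fold difference they had, and 12 at 2 weeks shrank by more than 1.5 times.

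In what follows the pairs are probes higher and lower, and the cause of the changes was not tested unless named. With normexp, 752 were higher at 1 week, 1688 lower at 2 weeks, 1542 and 1707 differed in mock at 1 against 0 weeks, 4571 were higher in mock at 2 against 0 weeks and 2064 at 2 against 1, 169 were lower in both weeks, and 167 moved down by 4-fold between weeks. Its correlations were −0.39 and −0.41 for MeJA at 2 weeks with mock 0 to 1 week, and −0.066 (Spearman) for MeJA at 1 week with mock 0 to 2 weeks; under quantile normalization these were −0.41 and −0.43, and −0.10 and −0.12. Spike-in scaling gave 2330 and 597 at 1 week, 401 and 22574 at 2 weeks, 14638 and 3199 for mock at 2 against 0 weeks and 15195 and 1509 at 2 against 1, since it shifts every probe of an array alike, and 90 higher in both weeks. With the brightest spike-ins included these were 2683 and 498, 493 and 21043, 16026 and 2780, 16104 and 1377, and 108. Probes lower in both weeks were 422 under spike-in scaling (400 if independent) and 329 with the brightest included (310 if independent).

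Turned signs are named here only for list medians outside the central 95% of random lists; medians inside that range turned as well. Spike-in scaling, which moved every median by 0.27 at 1 week and by −1.97 at 2 weeks, turned at 1 week those of pathogenesis-related proteins (0.025), antioxidant enzymes (0.023) and reference genes (0.040). At 2 weeks it turned nicotine and polyamine synthesis (−0.83), proteinase inhibitors (−0.53), antenna proteins (−0.49), photosystems (−0.59), chlorophyll synthesis (−0.58), cytosolic (−1.12) and plastid ribosomal proteins (−0.26), cell division (−1.08) and cell wall (−1.40). With the brightest spike-ins included the shifts were 0.34 and −1.79, and the 3 medians at 1 week were 0.091, 0.089 and 0.11, joined by starch and sugar (0.043). In the order given, those at 2 weeks were −0.65, −0.34, −0.31, −0.41, −0.40, −0.93, −0.076, −0.90 and −1.21. The 4 brightest spike-ins alone gave a shift of −1.61, which left plastid ribosomal proteins at 0.10 and turned the other 8. Setting MeJA at 2 weeks against mock at 1 week gave 1777 and 1584, and turned jasmonate biosynthesis (0.54), proteinase inhibitors (−0.21), MYB factors (0.042), ethylene (0.031), cell division (−0.074) and cell wall (−0.031).

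Keeping only probes well above background on all 5 arrays, which tests fewer probes, gave 645 and 656 at 1 week, 1389 lower in mock at 1 against 0 weeks, 4558 higher at 2 against 0, 2170 higher at 2 against 1, and 183 lower in both weeks. With no filter and no bounds there were 2300 and 2352 at 1 week, 16948 and 6133 at 2 weeks, 4444 lower in mock at 1 against 0 weeks, and 995 and 664 in both, where independent lists would share 891 and 330, so that the excess of those higher was small. At 4-fold there were 311 and 109 at 1 week, 1481 and 424 at 2 weeks, 411 and 530, 1950 and 2895, and 526 and 1451 in mock at 1 against 0, 2 against 0 and 2 against 1, and 58 and 16 in both weeks, the stricter threshold being the cause.

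The limma counts of 271 and 115 were 9 and 3 under quantile normalization, 35 and 11 without the variance trend, and 168 and 55 on probes well above background on all 5 arrays. Without the week term limma gave 0 and 0 on the same 4 arrays (1031 at an unadjusted p under 0.05) and 0 and 0 on 5 arrays (553). Also without it, and with other arrays, were fits with the slide as block on 5 arrays (12 and 2), within slide 2 on 3 arrays (937 and 190) and without the 2-week mock array but with mock at 0 weeks (10 and 0), so each changes more than 1 choice. Signal over background limits the dim genes: of differences from 2-fold at 2 weeks, 417 higher and 1078 lower rest on a bound.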

Other observations

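No explanation is tested in this part, and the values with genes at their bound were chosen only after the results were seen. Among lists not described above, antioxidant enzymes, which remove reactive oxygen, had 2 genes higher and 2 lower of 64 at 1 week, with a median of −0.25 (percentile 1.27) that was −0.15 under quantile normalization and 0.023 under spike-in scaling, and 15 higher and 1 lower at 2 weeks, with a median of 0.59 (percentile 76.6) that was 0.20 under quantile normalization, −1.38 under spike-in scaling and 0.19 against mock at 1 week. Glutathione S-transferase 12 (TC138305) was higher in both weeks (1.04 and 2.18), as was peroxiredoxin Q (Nta.26925, 1.33 and 1.87). NAC factors, many of them regulators of senescence, had medians of −0.53 (percentile 0.33; −0.26 under spike-in scaling) and −0.43 (percentile 11.8; −0.70 under quantile normalization), and WRKY factors had a median of −0.43 (percentile 9.83) at 2 weeks, with 5 lower and 0 higher of 22. MYB factors had medians of −0.12 (percentile 23.8) and −0.50 (percentile 1.17), the latter −0.23 under normexp and 0.042 against mock at 1 week. AP2/ERF factors stood at −0.29 (percentile 3.36), or −0.41 (percentile 0.17) with genes at their bound, and at 0.20 (percentile 38.8), the latter −0.07 under quantile normalization and −1.77 under spike-in scaling. Cell wall genes stood at 0.09 (percentile 99.7; 0.16 under quantile normalization) and 0.57 (percentile 98.3), the latter 0.26 under quantile normalization, −1.40 under spike-in scaling and −0.031 against mock at 1 week. Cytosolic and plastid ribosomal proteins had medians of 0.07 and 0.18 at 1 week (percentiles 100 and 99.98; 0.03 for the former under normexp and 0.30 for the latter under quantile normalization), and cell division genes −0.01 (percentile 75.2).

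The remaining medians are given for 1 and then 2 weeks. Spike-in scaling moved them by 0.27 and −1.97, which put every median at 2 weeks below 0 and those at 1 week between −0.27 and 0 above it. Phenylpropanoid synthesis stood at −0.08 (percentile 29.3; −0.23 and percentile 2.61 with genes at their bound) and −0.05 (percentile 19.1; 0.07 under normexp, −0.17 under quantile normalization and 0.17 against mock at 1 week), with caffeoyl-CoA O-methyltransferase Nta.1152 (2 of 3 probes), of lignin synthesis, at −1.0 and −1.89. Terpenoid synthesis stood at −0.00 and 0.04 (−0.37 under quantile normalization), chlorophyll breakdown at 0.03 and −0.04 (−0.71, percentile 4.61, under quantile normalization and 0.38 against mock at 1 week), and autophagy at −0.12 and −0.02 (−0.64, percentile 5.69, under quantile normalization). Proteases stood at −0.06 (−0.16 under normexp) and −0.02 (−0.13 under quantile normalization), with vacuolar processing enzyme 1b (TC166456) at −0.71 and −2.05. Senescence-associated genes had 4 higher and 0 lower of 10 at 2 weeks, with a median of 0.47 (percentile 68.9) that was −1.50 under spike-in scaling and 0.017 against mock at 1 week. Pathogenesis-related proteins had 18 genes higher and 12 lower of 70 at 2 weeks (12 and 15 under quantile normalization) and stood at 0.22 (percentile 18.6), but at −0.14 under quantile normalization, −1.75 under spike-in scaling and −0.14 against mock at 1 week, with the elicitor-inducible glucanase Nta.8405 lower (−3.46). Nitrogen genes stood at −0.21 (percentile 5.96) and 0.41 (percentile 64.7), the latter −0.19 with genes at their bound, −0.03 under quantile normalization and −1.56 under spike-in scaling. Abscisic acid genes stood at −0.26 and −0.16, the latter −0.63 (percentile 2.15, 1 higher and 5 lower) under quantile normalization. Auxin genes stood at −0.09 and 0.08 (0.00 and 0.02 under quantile normalization). Cytokinin and gibberellin genes stood at −0.17 and 0.06, or −0.43 and −0.96 with genes at their bound, −0.31 and 0.23 under normexp, and 0.28 at 2 weeks under quantile normalization. Heat shock proteins stood at −0.13 and 0.08, the latter −0.23 (percentile 1.9) under quantile normalization. Peroxidases stood at −0.20 and 0.11, lipid transfer and cuticle genes at −0.23 and 0.35, and glandular trichome markers at −0.53 and 0.82 over 3 genes, the 2-week values being −0.34, −0.27 and −0.66 against mock at 1 week. At 2 weeks peroxidases stood at 0.37 under normexp, and lipid transfer and trichome genes at 0.10 and 0.29 under quantile normalization. Antenna, photosystem, Calvin cycle and chlorophyll synthesis genes had medians of −0.32, −0.23, −0.10 and −0.03 at 1 week, which were −0.01, 0.04, −0.05 and 0.11 under quantile normalization, and ethylene genes −0.12, which was 0.03. Reference genes stood at −0.23 (percentile 0.60) and 0.34 (percentile 7.08), 0.040 and −1.64 under spike-in scaling and −0.07 at 2 weeks under quantile normalization. In the vascular and phloem list 1 gene had signal and none a measured MeJA difference, and the list of plastid and mitochondrial genome transcripts matched 0 genes.

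Over the 21464 probes well above background on all arrays, the log2 levels of mock and MeJA at 1 week had a Pearson correlation of 0.966 across probes, mock at 1 week and MeJA at 2 weeks one of 0.952, mock and MeJA at 2 weeks one of 0.878, and mock at 0 and 2 weeks one of 0.756. The array of mock at 0 weeks differed from the other 4 by 2-fold at 1102 probes.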
